A study of Mus musculus with 29 samples.

How the data were processed

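Gene expression was measured in 29 mouse libraries from 8 groups. LSK cells (lineage-negative, Sca-1-positive, Kit-positive blood stem and progenitor cells) were profiled after transplantation into hosts with a wild-type niche (6 libraries) or a niche that lacked 1 copy of Wnt5a (5 libraries). Of the niche itself, 3 sorted populations were profiled, each in 3 wild-type (WT) and 3 Wnt5a-haploinsufficient libraries. They are named EC for endothelium, OBC for bone-forming (osteoblastic) cells and MSC for mesenchyme. Cells were sorted by flow cytometry into lysis buffer, per the labels' protocols. The LSK libraries were made with Smart-seq2 and the niche libraries with barcoded, pooled cDNA carrying unique molecular identifiers (UMIs), both with Nextera XT, per the labels' protocols.

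The deposited LSK table holds raw read counts per Ensembl gene, and the deposited niche table holds counts of UMIs per Ensembl gene. STAR and featureCounts on the mm10 (GRCm38) genome are named without versions in the submitters' processing notes. How UMIs were collapsed, which annotation release was used and whether strand was used in counting are not given in the sources used here. Both tables hold whole numbers with different totals per library, and no column was left out. The LSK table has 38924 genes, of which 8511 are 0 in every library, and the niche table has 18194 genes, of which 2264 are 0 in every library. A further 28 spike-in entries in the niche table were kept out of the library totals. Gene symbols were found for 37607 and 17973 of the IDs in a table of Ensembl gene names. Coordinates come from the GENCODE mouse annotation of GRCm38.

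LSK totals ran from 1254553 to 5775459 reads and niche totals from 10635 to 117989 UMIs. Reads of Smart-seq2 libraries are not independent molecules, so binomial intervals and floors cover counting error only. Shares of single libraries carry exact Clopper-Pearson intervals at 95% confidence, and the floor of detection was taken as 3 counts of a library's total. Library-scaled counts (CPM) of named genes were computed from the deposited counts with TMM-scaled totals, and CPM of Wnt5a with plain totals.

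Each table was fitted with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood fit). A gene passed the test at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in the comparison. The LSK fit held 11 libraries in 2 groups. All 18 niche libraries entered 1 fit with 6 group means, so that the small groups shared 1 estimate of the spread. From it came Wnt5a against WT within EC, OBC and MSC, the mean of these 3 differences, the interaction of genotype with population, and each population against the mean of the others. Log2 fold changes are Wnt5a over WT, and their standard error (SE) is the log2 fold change divided by the square root of edgeR's F statistic. The common biological coefficient of variation was 0.448 for LSK and 0.318 for the niche. Every adjusted p of a gene in the text is from edgeR's quasi-likelihood test unless another method is named. Replicate numbers of the niche libraries are all different and no LSK label pairs samples, so libraries were compared as independent. Whether niche libraries of different populations come from the same animals is not given in the labels.

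Gene lists from textbook knowledge were written before the data were examined, 25 for LSK and 31 for the niche. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. This gave 23 tested lists for LSK and 14 for each niche comparison. Camera was run again with an estimated correlation, and fry gave a second set test. Members past the test were counted over all genes and adjusted over the list alone. The tests, the alternatives set in advance and the rule for named genes were also fixed before the data were examined. That rule named Wnt5a; the 10 higher and 10 lower genes with the smallest p among those past the test, without predicted or unnamed genes; and up to 4 tested members with the smallest p from each list past camera. The same number came always from 4 lists, among them the actin regulators, WNT5A receptors and non-canonical WNT signalling, and the stem cell or niche factor list. Between populations it named the 8 higher genes with the smallest p among folds over 4, with Pecam1, Alcam and Ly6a. Of the list members so named, the text gives some and leaves out others. Results of the fourth list as a whole and of 1 gene that the rule named in OBC are not reported here. Shares of reads were compared between groups with exact two-sided permutation tests over 10 measures per comparison, with Benjamini-Hochberg adjustment over those measures.

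Before use, the test was run on counts simulated from the real means and library sizes, with 200 genes changed by known folds. Recovery is a share of the changed genes that passed the filter, which were fewer than 200. Sample structure beside the groups was not simulated, so the false calls do not cover it. Fewer niche genes were run (801 to 920) than in the real fit (1099), so recovery there is a rough guide. For LSK (12762 genes run), 16.9% of 2-fold, 70% of 4-fold and 95.4% of 8-fold changes were recovered, with 8 false calls. The same shares were 25.8%, 85.4% and 98.4% for EC (851 genes), 18.2%, 45.8% and 88.9% for OBC (828 genes), and 8.47%, 61.3% and 92.5% for MSC (905 genes). False calls numbered 5, 3 and 0. Averaged over the populations (839 genes), 83.6% of 2-fold changes and 100% of 4-fold and 8-fold changes were recovered with 6 false calls. The interaction (832 genes) recovered 4.17%, 36.2% and 67.7% with 5 false calls. Recovery of 4-fold differences between populations was 98.2% for EC (848 genes), 98% for OBC (801 genes) and 98.1% for MSC (920 genes).

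Alternatives set before the data were examined were RLE scaling, no filter and a filter at 5 CPM, DESeq2 1.42.0, limma voom with sample weights, a fit that was not robust, each library left out in turn, haemoglobin, immunoglobulin, mitochondrial and sex-linked genes left out, and fits of 1 population alone. For LSK the log2 library total as a covariate and the removal of Wnt5a replicates 4 and 5 were among these. The label numbers of these replicates have 3 digits and those of all other LSK libraries have 4, so the numbers may mark another series of animals with Wnt5a samples only; what they mean is not given. The filter at 5 CPM is stricter than the main one in LSK (12514 genes tested against 13098) and looser in the niche (12137 against 1099), where 5 CPM is under 1 UMI. Alternatives added after seeing the data were a niche filter with a minimum count of 20 (419 genes tested), niche libraries thinned to 10635 UMIs, removal of genes that overlap ribosomal RNA, removal of satellite, olfactory receptor and mitochondrial genes in LSK, removal of LSK Wnt5a replicates 1 and 3, EC without WT replicate 14 and haemoglobin genes, the lists with no filter, removal of each library's trend with exon length, and fits with sets of niche libraries whose numbers lie 6 apart as a block. Chance was assessed with other splits of the samples, at most 100 per comparison. No library had a total under 0.1 of its table's median, so an exclusion of such libraries removed nothing. Figures were drawn with matplotlib 3.10.9.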

Results

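Blood stem and progenitor cells that had regenerated after transplantation were profiled together with 3 cell populations of the niche that surrounds such cells. The LSK cells came from 6 wild-type (WT) and 5 Wnt5a-haploinsufficient niches, where 1 copy of the gene for the secreted signal WNT5A is missing. Each niche population (EC, OBC and MSC) was profiled in 3 WT and 3 Wnt5a libraries. LSK libraries held 1254553 to 5775459 reads in WT and 1573560 to 3690114 in Wnt5a, with 16341 to 24603 genes detected per library. Totals in the niche were 83254 to 117989 UMIs for EC WT and 18542 to 106757 for EC Wnt5a. They were 10635 to 29772 for OBC WT and 13726 to 17874 for OBC Wnt5a, the shallowest groups. MSC libraries held 37352 to 50421 UMIs in WT and 19999 to 48279 in Wnt5a. The comparisons address how a niche with less WNT5A relates to gene expression in regenerating stem cells, with actin regulation as the named theme, and in the niche cells themselves.

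Wnt5a itself (ENSMUSG00000021994, GRCm38 chromosome 14, 28504750 to 28527448, plus strand) was at the edge of detection in LSK cells. WT replicates 1 to 4 had 0 reads each and WT replicates 5 and 6 had 1 read each. Wnt5a replicates 1 to 5 had 5, 1, 3, 0 and 1 reads. The means were 0.823 ± 0.836 CPM (SD, n = 5) and 0.118 ± 0.183 CPM (SD, n = 6), where 3 reads correspond to 0.519 to 2.39 CPM across the WT libraries. The gene did not pass the low-count filter, so no fold change is given. The genotype in the labels is that of the niche, so Wnt5a in LSK cells does not check the labels, and its level in the niche libraries was not analysed here.

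In LSK cells from Wnt5a niches, 2 protein-coding genes fell. Sephs2, which makes the selenium donor for selenoproteins, was at 1.95 ± 0.769 CPM (SD, n = 5) against 25.2 ± 16.9 CPM (SD, n = 6), a log2 fold change of -3.63 (SE 0.54, edgeR adjusted p = 0.0272). Ap2b1, a subunit of the clathrin adaptor used in endocytosis, was at 36.8 ± 7.03 against 91.6 ± 8.36 CPM, a log2 fold change of -1.32 (SE 0.21, edgeR adjusted p = 0.0451). All 5 Wnt5a libraries lay below all 6 WT libraries for both genes. The gene that rose was the predicted transcript Gm10715 (ENSMUSG00000096201, log2 fold change 4.35, SE 0.64, edgeR adjusted p = 0.0272). Gm10715 is made of satellite repeat sequence and fell outside the naming rule, so it was named after its value was seen. Its reads can be shared with near-identical copies, and all 12 tested satellite transcripts had positive log2 fold changes (3.54 to 4.35, median 3.89). Satellite transcripts took 2.64 ± 2.49% of reads in Wnt5a and 0.217 ± 0.127% in WT (exact permutation p = 0.00433, Benjamini-Hochberg adjusted p = 0.0433 over 10 measures). Reads of the mitochondrial genome took 4.97 ± 2.55% and 2.55 ± 0.703% (exact permutation p = 0.0216, Benjamini-Hochberg adjusted p = 0.0866), with positive values for 27 of 28 tested mitochondrial genes. Sephs2 lies on chromosome 7 (127271879 to 127274055) and Ap2b1 on chromosome 11 (83299024 to 83405035) of GRCm38.

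**Figure D1:**
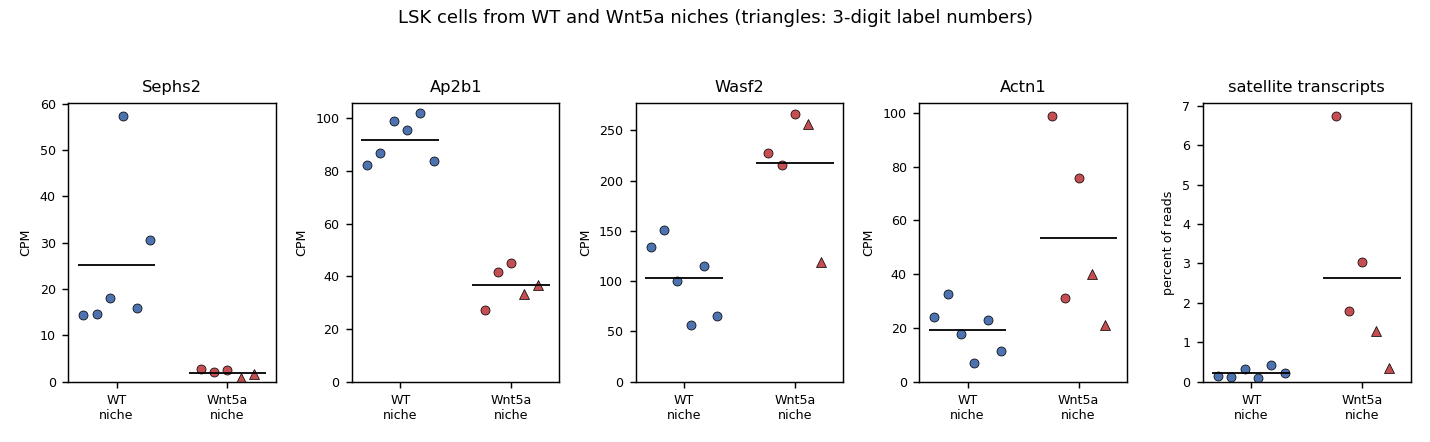
Normalised CPM of Sephs2, Ap2b1, Wasf2 and Actn1 and the percent of reads in satellite transcripts (y axes) in each LSK library of WT and Wnt5a niches (x axis); lines are group means and triangles mark Wnt5a replicates 4 and 5. Ap2b1 lies between 27.2 and 45.2 CPM in all Wnt5a libraries and between 82.4 and 102 CPM in all WT libraries, while Actn1 overlaps between the groups.

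Actin regulators were the gene group named by the study's title. Of 74 tested in LSK cells, 0 passed edgeR's test, 47 had positive and 27 negative log2 fold changes (median 0.17), and the list did not pass camera (adjusted p = 0.149, and 0.794 with an estimated correlation). Members with the smallest p were Wasf2, which switches on branched actin assembly (log2 fold change 1.07, SE 0.26, edgeR adjusted p = 0.0817), and the actin cross-linker Actn1 (1.48, SE 0.44, edgeR adjusted p = 0.116). Actb, cytoplasmic actin, was at 1770 ± 113 against 1269 ± 208 CPM (edgeR adjusted p = 0.128), and the non-muscle myosin heavy chain Myh9 was at 204 ± 56.3 against 117 ± 39.9 CPM (0.133). Adjusted over the list alone, 0 actin regulators passed. Arhgef7 and Dock2, which encode nucleotide exchange factors, did not pass either, with log2 fold changes of 1.35 (SE 0.30, edgeR adjusted p = 0.0607) and 0.71 (SE 0.20, edgeR adjusted p = 0.0964). Arhgap18 had -0.59 (SE 0.16, edgeR adjusted p = 0.0964). Among integrins and focal adhesion genes, 21 of 27 were positive (camera adjusted p = 0.149). Stem cell identity genes went both ways (19 of 35 positive, median 0.15 and mean -0.05, camera adjusted p = 0.961). Ltb, a lymphotoxin subunit, was at 18.2 ± 16.5 against 95.5 ± 42.3 CPM (edgeR adjusted p = 0.0676) and the adhesion molecule Esam was at 33.8 ± 10.4 against 68.2 ± 13.9 CPM (0.0902). The transcription factors Erg and Runx1 had log2 fold changes of 0.98 (edgeR adjusted p = 0.105) and 0.54 (0.138). Non-canonical WNT genes were also split (17 of 30 positive, camera adjusted p = 0.961). The receptor Fzd8 was at 16.6 ± 10.8 against 4.76 ± 4.58 CPM (edgeR adjusted p = 0.193) and the calcineurin subunit Ppp3r1 was at 113 ± 63.3 against 202 ± 43.0 CPM (0.168).

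The test covered 13098 genes, of which 3 passed and 2414 had an unadjusted p under 0.05 where chance gives 654.9. DESeq2 called 656 genes and limma voom 90. Of the 23 lists tested, 0 passed camera, with 0 at an estimated correlation, 0 by fry and 11 by fry's test of change in either direction. The count of 3 was 0 without any 1 of WT replicates 1, 2, 3, 4 or 6 or Wnt5a replicates 2, 3 or 4 (unadjusted counts 1830 to 2405), 2 without WT replicate 5, 16 without Wnt5a replicate 1 and 1114 without Wnt5a replicate 5. Without satellite, olfactory receptor and mitochondrial genes it was 0 (Sephs2 edgeR adjusted p = 0.0501, Ap2b1 edgeR adjusted p = 0.0555).

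Among the libraries with 4-digit label numbers (6 WT, 3 Wnt5a), 425 genes were higher and 457 lower. The label numbers of these 3 Wnt5a libraries (8471, 8491 and 8541) lie below those of WT replicates 3 to 6 (8551 to 8581). Genotype and label order are thus in part confounded in this set, and what the order means is not given. A split that put WT replicates 3, 4 and 6, late in label order, against the rest of the set gave 653 genes. The rest held all 3 Wnt5a libraries, so this split does not part label order from genotype. The naming rule does not cover this set, so its genes were taken from the fixed lists after their values were seen. Actin regulators changed in both directions there. Wasf2 (log2 fold change 1.19, SE 0.27, edgeR adjusted p = 0.0213), Actn1 (1.83, SE 0.44, edgeR adjusted p = 0.0268) and the filament cross-linker Flna (0.80, SE 0.20, edgeR adjusted p = 0.0327) were higher. Arpc3, a subunit of the Arp2/3 complex (-1.41, SE 0.28, edgeR adjusted p = 0.0142), Nckap1, a partner of the WAVE proteins (-2.27, SE 0.46, edgeR adjusted p = 0.0159), and Dstn, which severs filaments (-1.40, SE 0.33, edgeR adjusted p = 0.0265), were lower. These were the 6 of 76 tested actin regulators that passed. Whether that is more than the 882 of 13910 over all genes was not tested. The list as a whole did not pass camera (adjusted p = 0.359), which asks for a shared direction. The exchange factor genes Arhgef7 (1.43, SE 0.26, edgeR adjusted p = 0.0126), Dock2 (0.90, SE 0.19, edgeR adjusted p = 0.0162) and Arhgef1 (0.93, SE 0.25, edgeR adjusted p = 0.0447) were higher. The growth regulator Myc was higher (1.22, edgeR adjusted p = 0.0147). Granulocyte and monocyte genes went both ways, with Mpo (1.13, edgeR adjusted p = 0.0142), Irf8 (1.73, edgeR adjusted p = 0.0194) and Calr higher and Elane (-2.65, edgeR adjusted p = 0.0362), Prtn3, Lyz2 and Fcgr3 lower. Of 14 tested B and plasma cell genes, Cd79a (-4.04, edgeR adjusted p = 0.0368) and Cd74 (-1.26, edgeR adjusted p = 0.0265) were lower. Of 9 tested T and NK cell genes, Klrb1c was lower (-2.45, edgeR adjusted p = 0.0442). Satellite reads took 3.86 ± 2.57% in these 3 Wnt5a libraries (exact permutation p = 0.0119) and mitochondrial reads 4.44 ± 1.31% (exact permutation p = 0.0238). Of the 13910 genes tested, 882 passed and 3692 had an unadjusted p under 0.05; 846 of the 882 were also tested in all libraries, 843 with the same sign, although these libraries are part of that test. The 2 Wnt5a libraries with 3-digit numbers had no WT partner in their label series and differed from each other, with Wasf2 at 256 and 119 CPM and Nckap1 at 8.30 and 82.0 CPM in replicates 4 and 5. Leaving out replicate 5 alone gave 1114 genes, and leaving out replicate 4 alone gave 0. The count therefore turned on replicate 5 and not on the label series as such. In replicate 5, immunoglobulin transcripts took 10.2% of reads.

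The 3 niche populations carried different transcripts. EC had more of the heat shock gene Hspa1a than the mean of the other populations (log2 difference 2.71, SE 0.37, edgeR adjusted p = 1.54e-07), and also more Ushbp1, Depp1, Trp53i11, Sec14l1, Slc28a2, Hspa1b and Hsp25-ps1 (2.09 to 3.12). OBC had more of the type I collagen chains Col1a1 (4.49, SE 0.30, edgeR adjusted p = 4.29e-17) and Col1a2 (4.12, SE 0.30, edgeR adjusted p = 1.00e-14) and of bone sialoprotein Ibsp (5.76, SE 0.51, edgeR adjusted p = 5.67e-13). Hp, Anp32b, Slc17a9 and Snora73b were higher in OBC as well (3.47 to 4.80). MSC had more of the collagen chain Col3a1 (2.53, SE 0.30, edgeR adjusted p = 2.29e-08), of Fn1, Dcn, Clec3b, Pi16, Smoc2 and Igfbp6 (2.19 to 4.35), and of the antibody heavy chain Igha (3.27, SE 0.33, edgeR adjusted p = 2.29e-08). The endothelial surface gene Pecam1 was lower in OBC (-0.74, SE 0.26, edgeR adjusted p = 0.0178) and did not pass in EC (0.52, edgeR adjusted p = 0.0595) or MSC (0.23, edgeR adjusted p = 0.674). Ly6a, which encodes Sca-1, was higher in EC (0.91, edgeR adjusted p = 0.00138), lower in OBC (-1.46, edgeR adjusted p = 4.58e-05) and at 0.55 in MSC (edgeR adjusted p = 0.156), and Alcam did not pass the filter. Of 1099 genes tested, 268 were higher and 172 lower in EC, 212 higher and 294 lower in OBC, and 53 higher and 21 lower in MSC. RLE scaling in place of TMM moved the median of all genes by 0.11 in EC and -0.12 in OBC. Whether Pecam1 passed in EC depended on the processing, since it did with RLE (0.62, edgeR adjusted p = 0.0221), with no filter (0.91, edgeR adjusted p = 0.00636) and without any 1 of EC WT replicate 14, OBC WT replicate 9, OBC Wnt5a replicate 10 or EC Wnt5a replicate 17. The call of Pecam1 in OBC was lost without OBC WT replicate 8 (edgeR adjusted p = 0.112). The count of 74 in MSC was 45, 38, 46, 49, 41 and 42 without MSC WT replicates 2 and 3, MSC Wnt5a replicates 4 and 5, EC Wnt5a replicate 17 and MSC Wnt5a replicate 6.

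In EC of the Wnt5a genotype, 4 genes rose and 0 fell, and all 4 belong to the granules or cytosol of neutrophils. Ngp, a neutrophil granule protein, was at 486 ± 105 against 63.2 ± 23.1 CPM (SD, n = 3 each; log2 fold change 2.85, SE 0.50, edgeR adjusted p = 0.000661). S100a9 and S100a8, which form calprotectin, were at 938 ± 531 against 207 ± 53.3 CPM (2.29, SE 0.43, edgeR adjusted p = 0.00109) and 697 ± 292 against 148 ± 99.0 CPM (2.16, SE 0.46, edgeR adjusted p = 0.00727). Ltf, which encodes lactoferrin, was at 215 ± 119 against 15.9 ± 27.6 CPM (3.13, SE 0.74, edgeR adjusted p = 0.0305). That WT mean lies under the floor of 3 UMIs, so the size of this fold change is loose, and it ran from 2.66 to 5.53 with 1 library left out, the highest without EC WT replicate 15. The neutrophil list rose as a group, with 4 of 5 tested members past the test, 5 of 5 adjusted over the list alone, and a median of 2.29 (camera adjusted p = 8.62e-16, and 0.00178 with an estimated correlation). Genes of oxidative phosphorylation were lower as a list, with 15 of 17 members negative, 0 past over all genes and 1 adjusted over the list alone (median -0.67, camera adjusted p = 0.000233, but 0.133 with an estimated correlation). Examples were Cox7a2 (-1.40, SE 0.44, edgeR adjusted p = 0.196) and Ndufa4 (-0.94, SE 0.40, edgeR adjusted p = 0.487). Immediate early genes were higher as a list, with 16 of 19 positive and 0 past (median 0.49, camera adjusted p = 0.000292, but 0.526 with an estimated correlation), such as Ier2 (0.94, edgeR adjusted p = 0.510) and Klf2 (0.78, edgeR adjusted p = 0.597). Transcripts that overlap ribosomal RNA took 7.77 ± 4.08% of UMIs in Wnt5a and 3.06 ± 1.22% in WT (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Immunoglobulin (0.0503 ± 0.0192 against 0.0131 ± 0.00722%) and mitochondrial transcripts (2.55 ± 0.0896 against 1.68 ± 0.669%) were higher with the same p. Haemoglobin was not higher on average (5.08 ± 1.25 against 9.59 ± 12.7%), with 24.3% in EC WT replicate 14. EC WT replicates 13 and 15 had 1.90 and 2.57%, below the 3.80 to 6.28% of the EC Wnt5a libraries.

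Actin regulators in EC were split, with 15 of 27 positive and 0 past (camera adjusted p = 0.753). Their smallest p belonged to Coro1a, an actin-binding protein of leukocytes, at 56.0 ± 25.9 against 5.63 ± 9.75 CPM (edgeR adjusted p = 0.525), and the integrin activator Tln1 was at 415 ± 195 against 201 ± 110 CPM (edgeR adjusted p = 0.597). Arhgdia (0.51) and Rhoa (-0.22) did not pass. The niche factors did not pass (7 tested, camera adjusted p = 0.753). Kitl, the stem cell factor, had -0.42 (SE 0.40, edgeR adjusted p = 0.807) and the chemokine Cxcl12 had 0.29 (SE 0.40, edgeR adjusted p = 0.892). Non-canonical WNT genes had too few tested members for a list test, with Jun at 0.74 (edgeR adjusted p = 0.597) and Ppp3ca at 0.30 (0.893). Of 1099 genes tested in EC, 4 passed and 89 had an unadjusted p under 0.05 where chance gives 54.95. The count was 22 without EC WT replicate 15 and 2 without EC Wnt5a replicate 17, where S100a9 (edgeR adjusted p = 0.178), S100a8 (0.127) and Ltf (0.264) did not pass. The immediate early list was lost without EC WT replicate 14 (camera adjusted p = 0.311), the library with 24.3% haemoglobin (95% exact Clopper-Pearson interval 24.0 to 24.6%). S100a8 did not pass without EC WT replicate 13 (edgeR adjusted p = 0.139), nor Ltf without EC WT replicates 13 (0.184) and 14 (0.129).

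**Figure D2:**
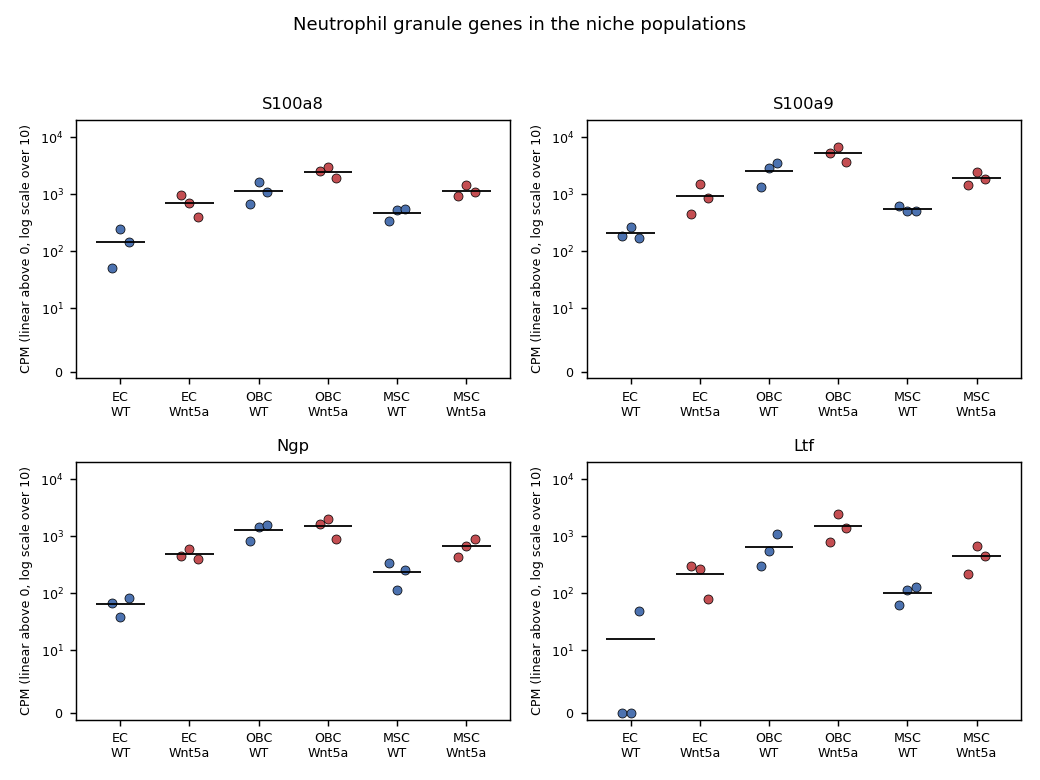
Normalised CPM of S100a8, S100a9, Ngp and Ltf (y axes, logarithmic above 10 and linear below) in each EC, OBC and MSC library of the WT and Wnt5a genotypes (x axis); lines are group means of 3 libraries. Means are higher in Wnt5a in each population and gene, from 486 against 63.2 CPM for Ngp in EC to 1520 against 1276 CPM for Ngp in OBC, which did not pass the test.

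In OBC of the Wnt5a genotype, genes of bone matrix and of the mitochondrial genome fell. Col1a1 was at 2061 ± 1015 against 7632 ± 3928 CPM (SD, n = 3 each; log2 fold change -1.89, SE 0.43, edgeR adjusted p = 0.0122). Col1a2 was at 2788 ± 986 against 9058 ± 5905 CPM (-1.72, SE 0.45, edgeR adjusted p = 0.0430). Spp1, which encodes osteopontin, was at 316 ± 79.1 against 1820 ± 812 CPM (-2.55, SE 0.67, edgeR adjusted p = 0.0411). Ibsp did not pass, at 562 ± 492 against 2180 ± 1035 CPM (-1.93, SE 0.55, edgeR adjusted p = 0.0755). The osteoblast list fell as a group, with 7 of 7 tested members negative, 3 past over all genes and 5 adjusted over the list alone (median -1.72, camera adjusted p = 1.38e-08, but 0.0534 with an estimated correlation; fry adjusted p = 0.0283). Of 13 tested mitochondrial genes, all were negative (median -1.89) and 7 fell. These were mt-Nd5 (-3.25, SE 0.56, edgeR adjusted p = 0.000546), mt-Nd3 (-3.36, SE 0.62, edgeR adjusted p = 0.000931), mt-Nd1 (-2.36), mt-Nd2 (-2.49), mt-Cytb (-1.91), mt-Nd4 (-1.86) and the ribosomal RNA mt-Rnr1 (-1.89). The mitochondrial share of UMIs was 6.81 ± 2.81% against 15.4 ± 2.96% (exact permutation p = 0.1, the smallest possible). Haemoglobin took 8.51% of UMIs on average (5.16, 8.41 and 11.96% in Wnt5a replicates 10 to 12) against 4.47% (3.42 to 6.47%; exact permutation p = 0.2), and its 4 tested genes were at 0.70 to 0.90, with 0 past the test. Also lower were Gm13340, Gm13341 and the cytokine signalling factor Stat3 (-3.80, SE 1.03, edgeR adjusted p = 0.0459), which the naming rule left out and which were named after their values were seen. Whether Gm13340 and Gm13341 share reads with mitochondrial genes was not tested. Rps9, a ribosomal protein with processed copies that can share its reads, was the 1 gene that rose (1.81, SE 0.45, edgeR adjusted p = 0.0257). Col1a1 lies on chromosome 11 (94936224 to 94953042), Col1a2 on chromosome 6 (4504814 to 4541544) and Spp1 on chromosome 5 (104435118 to 104441050) of GRCm38.

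**Figure D3:**
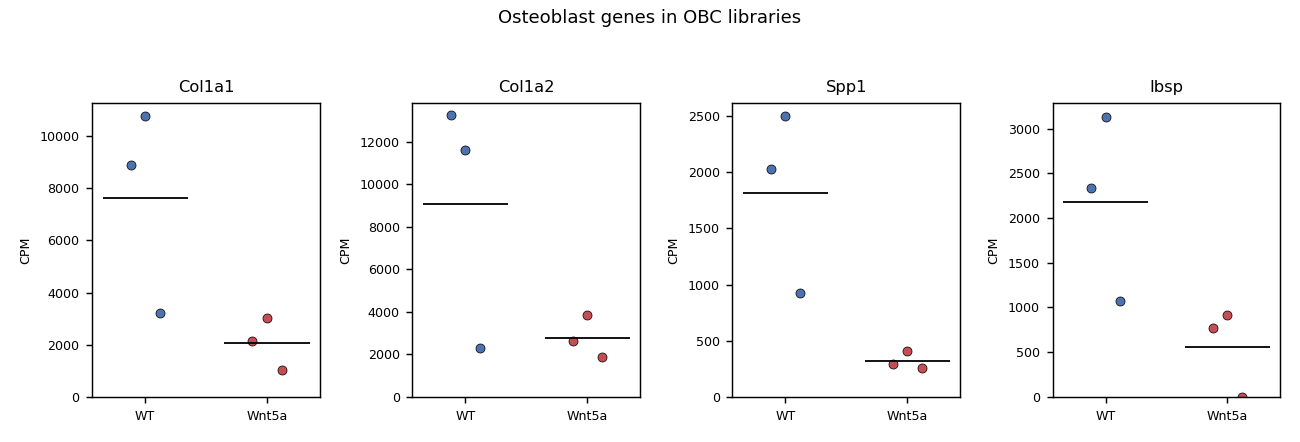
Normalised CPM of Col1a1, Col1a2, Spp1 and Ibsp (y axes) in each OBC library of the WT and Wnt5a genotypes (x axis); lines are group means of 3 libraries. Means are lower in Wnt5a for each gene, such as 316 against 1820 CPM for Spp1, while single libraries of the groups overlap for Col1a2.

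Among the other lists in OBC, extracellular matrix was lower (14 of 19 negative, 2 past, median -0.86, camera adjusted p = 0.00401, but 0.331 with an estimated correlation), with Sparc, a collagen-binding protein, at -1.22 (SE 0.46, edgeR adjusted p = 0.333). Niche factors were lower as a list (5 of 7 negative, 1 past, median -0.71, camera adjusted p = 0.0269, but 0.352 with an estimated correlation). Members past the test in the matrix and niche factor lists were among Col1a1, Col1a2 and Spp1. The same 3 genes passed in the osteoblast list, so the falls of these lists are not separate results. Cxcl12 was at 6474 ± 3844 against 10540 ± 2835 CPM (edgeR adjusted p = 0.607) and Cxcl14 had -1.39 (edgeR adjusted p = 0.545). The Notch ligand Dll4 had 0 UMIs in all WT libraries and 66.1 ± 57.3 CPM in Wnt5a, under the floor of 3 UMIs. Neutrophil genes were higher as a list (5 of 5 positive, 0 past over all genes, 3 adjusted over the list alone, median 1.04, camera adjusted p = 0.00400, but 0.251 with an estimated correlation), with S100a9 at 1.04 and Ltf at 1.39. Immediate early genes were higher as a list (14 of 19 positive, 0 past, median 0.26, camera adjusted p = 0.0269, but 0.595 with an estimated correlation), with Ier2 at 2.29 (SE 0.70, edgeR adjusted p = 0.113). Actin regulators were split (13 of 27 positive, camera adjusted p = 0.700), with Vasp, which extends filaments, at 1.61 (edgeR adjusted p = 0.333) and the Arp2/3 subunit Actr2 at 1.71 (edgeR adjusted p = 0.333). Rhoc (-1.04), Cdc42 (-1.14) and Rac1 (-1.44) did not pass. Of 1099 genes tested in OBC, 14 passed and 92 had an unadjusted p under 0.05. The count was 3 without OBC WT replicate 7, 4 without OBC WT replicate 8, 7 without OBC Wnt5a replicate 11, 5 without OBC Wnt5a replicate 12, and 3 without haemoglobin, immunoglobulin, mitochondrial and sex-linked genes. The last setting takes out the 7 mitochondrial genes among the 14 called. Without OBC WT replicate 7 the matrix (camera adjusted p = 0.0637), niche factor and neutrophil lists (both 0.0569) did not pass. Col1a1 did not pass without OBC WT replicates 7 (edgeR adjusted p = 0.0884) and 8 (0.162) or OBC Wnt5a replicate 12 (0.143). Spp1 and Col1a2 each passed in 1 of 6 fits with a library left out. The osteoblast list passed camera in each such fit (adjusted p 2.20e-14 to 1.93e-05), the niche factor list in 3 of 6 and the immediate early list in 1 of 6.

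In MSC of the Wnt5a genotype, 3 genes rose and 2 fell. Kitl, the growth factor that stem cells need from their niche, fell to 224 ± 131 from 803 ± 232 CPM (SD, n = 3 each; log2 fold change -1.96, SE 0.49, edgeR adjusted p = 0.0432). Sgk1, a kinase induced by glucocorticoids, fell to 459 ± 111 from 1525 ± 54.6 CPM (-1.78, SE 0.41, edgeR adjusted p = 0.0169). S100a9 rose (1.82, SE 0.41, edgeR adjusted p = 0.0169), as did the nuclear protein gene Anp32b (2.36, SE 0.51, edgeR adjusted p = 0.0138) and the ribosomal pseudogene Rps24-ps2 (2.18, SE 0.44, edgeR adjusted p = 0.0103), whose reads can be shared with Rps24. Ribosomal protein genes were higher as a list, with 32 of 37 positive, 0 past over all genes and 4 adjusted over the list alone (median 0.57, camera adjusted p = 1.09e-05, but 0.253 with an estimated correlation). Among them were Rpsa (1.59, edgeR adjusted p = 0.0600) and Rplp2 (1.30, edgeR adjusted p = 0.0724). Neutrophil genes were higher, with 5 of 5 positive, 1 past and 4 adjusted over the list alone (median 1.49, camera adjusted p = 8.60e-05, but 0.174 with an estimated correlation). Endothelial genes were lower, with 23 of 24 negative, 0 past and 1 adjusted over the list alone (median -0.65, camera adjusted p = 0.000126, but 0.253 with an estimated correlation). Gpihbp1, a capillary lipase anchor, was at 1709 ± 739 against 4275 ± 485 CPM (edgeR adjusted p = 0.0600), and Egfl7 was at 1809 ± 423 against 4130 ± 48.3 CPM (0.126). A change in the mix of sorted cells was not tested in MSC. The falls of Kitl and Sgk1 are thus not shown to lie within 1 cell type. Transcripts that overlap ribosomal RNA took 5.62, 14.6 and 12.4% of UMIs in MSC Wnt5a replicates 4 to 6 and 4.81 to 7.24% in WT (exact permutation p = 0.2). The mitochondrial share was 3.49 ± 0.894% in Wnt5a against 2.10 ± 0.260% in WT (exact permutation p = 0.1, the smallest possible). RLE in place of TMM moved the median of all genes by -0.20, and the list medians were then 0.37 for ribosomal proteins, 1.30 for neutrophil genes and -0.85 for endothelial genes.

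Actin regulators in MSC did not pass (12 of 27 positive, camera adjusted p = 0.505), with the bundling protein Fscn1 at 213 ± 99.1 against 537 ± 173 CPM (edgeR adjusted p = 0.144) and Tmsb4x, which binds actin monomers, at -0.56 (0.453). Cdc42ep3 (-1.58, edgeR adjusted p = 0.184), Rac1 (-0.98), Cdc42 (-1.02) and Rhob (-0.93) did not pass. Niche factors as a list did not pass (camera adjusted p = 0.476), with Ebf3 at 1.52 and Cxcl14 at -1.50 beside Kitl. Of 1099 genes tested in MSC, 5 passed and 203 had an unadjusted p under 0.05; with RLE scaling 9 passed, 3 higher and 6 lower. The count was 0 without MSC WT replicates 1 or 2 or MSC Wnt5a replicate 5 (unadjusted counts 130 to 172), 2 without MSC Wnt5a replicate 6, 14 without MSC Wnt5a replicate 4 and 16 without MSC WT replicate 3. Kitl and Sgk1 thus lost their calls in the fits with 0 genes. They also lost them without MSC Wnt5a replicate 6, where both called genes were higher. It was 0 with no filter (739 unadjusted) or with the filter at 5 CPM (737), which is looser than the main one here, 24 with a minimum count of 20, and 36 by DESeq2 and 59 by limma voom.

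Averaged over EC, OBC and MSC, 24 genes were higher and 10 lower in the Wnt5a genotype. Neutrophil transcripts led, with S100a9 (log2 fold change 1.72, SE 0.24, edgeR adjusted p = 3.06e-06), S100a8 (1.52, SE 0.25, edgeR adjusted p = 0.000117), Ltf (2.24, SE 0.38, edgeR adjusted p = 0.000117) and Ngp (1.55, SE 0.27, edgeR adjusted p = 0.000198). As a list, 4 of 5 neutrophil genes rose (median 1.55, camera adjusted p = 4.10e-15, and 0.00251 with an estimated correlation). The chaperone Hsp90aa1 (1.15, SE 0.25, edgeR adjusted p = 0.00423), Anp32b (1.15, SE 0.27, edgeR adjusted p = 0.0121) and the AP-1 subunit Jund (0.96, SE 0.24, edgeR adjusted p = 0.0203) also rose. So did Rps9 (1.02, SE 0.26, edgeR adjusted p = 0.0203), Rps24-ps2 and Rpl38-ps2. Mir6236 and Lars2 rose too (2.37 and 1.11), and both overlap sequence of ribosomal RNA. Of the 10 genes that fell, 4 were the semaphorin Sema7a (-2.63, SE 0.67, edgeR adjusted p = 0.0203), the cell cycle regulator Rgcc (-0.97, SE 0.25, edgeR adjusted p = 0.0220), the protease inhibitor Cst3 (-0.89, SE 0.24, edgeR adjusted p = 0.0262) and Kitl (-0.97, SE 0.29, edgeR adjusted p = 0.0474). Sema7a was at -1.25 (SE 0.46) in EC, -1.47 (SE 0.54) in MSC and -5.19 (SE 2.09) in OBC, so the size of its average is loose. Igfbp7 (-0.83), Son (-0.92), Gdpd3 (-1.80) and the transfer RNA mt-Ta (-1.87) fell too. Several of these calls depended on single libraries. With each of the 18 libraries left out in turn, the call was lost in 13 fits for Kitl, 13 for Igfbp7, 8 for Gdpd3, 7 for Cst3, 7 for Jund, 6 for Son and 6 for Rgcc, and in 0 for the 4 neutrophil genes and Hsp90aa1. The immediate early list (15 of 19 positive, 1 past, camera adjusted p = 0.00436, but 0.647 with an estimated correlation) and the ribosomal list (29 of 37 positive, 1 past, camera adjusted p = 0.0123, but 0.647 with an estimated correlation) were higher. The immediate early list of the average did not pass without EC WT replicate 14 (camera adjusted p = 0.117) or MSC Wnt5a replicate 6 (0.0513), nor the ribosomal list without EC WT replicate 15 (0.101). Actin regulators were split 13 to 14 (camera adjusted p = 0.983), and niche factors did not pass camera as a list (0.497). Of 1099 genes tested in the average, 34 passed, and with RLE scaling 29 did (16 higher, 13 lower). The count was 71 without EC WT replicate 14, 14 without MSC WT replicate 1, 15 without MSC Wnt5a replicate 5, 18 without OBC Wnt5a replicate 11, 20 without EC WT replicate 13 and 21 without MSC Wnt5a replicate 6. It was 17 without any 1 of OBC WT replicate 7, MSC WT replicate 2, OBC Wnt5a replicate 10 or EC Wnt5a replicate 18.

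The interaction test asked whether the genotype differences themselves differed between the populations. They did for 6 genes, which were 4 subunits of respiratory complex I encoded in the mitochondrial genome and the predicted genes Gm13340 and Gm13341. Whether reads of these predicted genes are shared with mitochondrial genes was not tested. The 6 genes are thus not shown to be separate results. For mt-Nd5 the log2 fold changes were 0.58 in EC, -3.25 in OBC and 1.05 in MSC (edgeR adjusted p = 0.00260), and for mt-Nd3 they were 1.16, -3.36 and -0.29 (edgeR adjusted p = 0.00261). The other genes were mt-Nd1 (edgeR adjusted p = 0.0246), mt-Nd4 (0.0425), Gm13340 (0.00662) and Gm13341 (0.00662). For Ngp (edgeR adjusted p = 0.171), S100a9 (0.666), Kitl (0.572), Col1a1 (0.521) and Spp1 (0.665), the genotype differences were not shown to differ between populations. The count of 6 was 2 without OBC WT replicate 7, 3 without OBC Wnt5a replicate 12, 10 without OBC WT replicate 9 and 15 without EC WT replicate 15. In contrast, mt-Nd5 and mt-Nd3 passed in each of the 18 fits with a library left out.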

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

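The tests of genomic DNA, of the label series, of blood carried along, of a lower share of osteoblasts and, by thinning, of depth in niche cells were chosen only after the results were seen; the others were set before.

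Satellite and mitochondrial reads were higher in LSK libraries of Wnt5a niches (satellite share 2.64 ± 2.49% against 0.217 ± 0.127%). Depth is argued against, since with the log2 library total as a covariate the median satellite log2 fold change was 4.01 (SE 0.728) and without it 3.89. The label series alone is argued against too, since the share was higher among the libraries with 4-digit numbers (3.86 against 0.217%, exact permutation p = 0.0119). Genomic DNA in the libraries stays open as a candidate explanation: 1589 genes of families that blood cells do not use took 0.0168% of reads against 0.00538% (exact permutation p = 0.0195). It does not cover Wnt5a replicate 4, where these families took 0.00597%, within the WT range, while satellite reads took 1.28% and mitochondrial reads 8.96%. In Wnt5a replicate 5 the families took 0.00623% and satellite reads 0.341%, both within the WT range. The niche genotype also stays open and was not tested apart from it.

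Neutrophil transcripts were higher in Wnt5a niche cells, with the 5 tested genes at a pooled log2 fold change of 1.54 (SE 0.123) over the populations. With all niche libraries thinned to 10635 UMIs the median of the 3 genes still tested was 1.61 (SE 0.405) and before thinning 1.55. Random thinning keeps each gene's expected share of UMIs and cannot undo a bias already present in shallow libraries. It therefore does not decide on depth. Blood carried along cannot be told apart from other sources. The neutrophil score (mean log2 CPM) rose by 1.44 (SE 0.178) and the haemoglobin score by 0.367 (SE 0.451), a difference of 1.08 (SE 0.471), but this rests in part on the 24.3% haemoglobin of EC WT replicate 14. Without that library the haemoglobin score rose by 0.764 (SE 0.220) and the difference was 0.683 (SE 0.292). In EC the scores changed by 2.07 (SE 0.307) and -0.115 (SE 0.781), a difference of 2.19 (SE 0.816). Without that library both rose, by 2.11 (SE 0.349) and 1.09 (SE 0.409), and the difference of 1.02 (SE 0.544) was under 2 SE. They changed by 0.914 and 0.797 in OBC and by 1.34 and 0.420 in MSC, with the same SE as in EC with all libraries. With EC WT replicate 14 left out, the haemoglobin score changed by 0.803 (SE 0.366) in OBC and 0.404 (SE 0.366) in MSC. A larger amount of RNA from neutrophils, by leaked RNA or by sorted cells, stays open, because departure of the granule genes from a common rise had a heterogeneity p of 0.0552 (Cochran's Q across genes, which are not independent) and S100a9 and S100a8 reached 5197 and 2486 CPM in OBC. Whether the sort gates remove neutrophils is not given in the labels. A change of the niche cells with the Wnt5a genotype also stays open and was not tested.

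Osteoblast genes were lower in OBC of the Wnt5a genotype (median log2 fold change -1.72 over 7 genes). After thinning, the 3 genes still tested had a median of -1.73 (SE 0.521). Random thinning keeps each gene's expected share of UMIs, so this value does not decide on depth. The median was -1.73 (SE 0.551) when haemoglobin, immunoglobulin, mitochondrial and sex-linked genes were left out. This test decides nothing on mitochondrial UMIs taking counts, because they took a smaller share in Wnt5a OBC and so could only raise the other genes there. In that fit Col1a1 passed and Spp1 and Col1a2 did not (both edgeR adjusted p = 0.0712). A lower share of osteoblasts among the sorted cells and lower expression in each osteoblast cannot be told apart: the neutrophil score rose over the endothelial score by 0.738 (SE 0.488), which is within its spread, and the haemoglobin score rose by 0.797 (SE 0.781). With EC WT replicate 14 left out of the fit, the haemoglobin score in OBC rose by 0.803 (SE 0.366), over 2 SE. The genotype stays open as a biological explanation that was not tested.

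Single libraries stood apart from the rest of their group in 4 of 58 checks, where chance gives 2.9. In LSK WT replicate 6, haemoglobin took 0.0256% of reads against 0.0581 to 0.0761% in the other libraries of the group. In LSK Wnt5a replicate 5, immunoglobulin transcripts took 10.2% of reads (95% exact Clopper-Pearson interval 10.1 to 10.2%) against 0.360 to 1.34%. In LSK Wnt5a replicate 3, Fzd8 was at 35.5 CPM against 8.82 to 14.8. In LSK Wnt5a replicate 5, Erg was at 68.3 CPM against 154 to 189.

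The genotype difference itself differed between EC, OBC and MSC for 6 genes by edgeR's interaction test. The adjusted p was 0.00260 for mt-Nd5, 0.00261 for mt-Nd3, 0.00662 for Gm13340, 0.00662 for Gm13341, 0.0246 for mt-Nd1 and 0.0425 for mt-Nd4. Gm13340 and Gm13341 were at -1.72 and -3.06 in OBC and at 1.39 and 1.40 in MSC on the log2 scale. Reads shared between them and mitochondrial genes were not tested for. Spike-in entries, which no comparison used, held up to 8 UMIs in a niche library and at most 0.0115% of its total.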

How the results depend on the processing

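Thinning, the filter at 20 counts, removal of genes that overlap ribosomal RNA or of satellite, olfactory receptor and mitochondrial genes, removal of LSK Wnt5a replicates 1 and 3 or of EC WT replicate 14 with haemoglobin genes, the lists with no filter, the exon length correction, and the fits and splits by sets of niche libraries were chosen after seeing the data; the other alternatives and splits were set before. No paired analysis was possible because niche WT and Wnt5a libraries share no replicate number and LSK numbers only follow sample order.

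For LSK, the 3 genes became 343 with no filter, 25 with a fit that was not robust, 32 without haemoglobin, immunoglobulin, mitochondrial and sex-linked genes, 656 with DESeq2, 90 with limma voom, 882 without Wnt5a replicates 4 and 5, and 144 with the exon length trend removed. They became 0 with the library total as covariate (2025 unadjusted), without Wnt5a replicates 1 and 3 (1979) and without satellite, olfactory receptor and mitochondrial genes (2381). With 1 library left out they ran from 0 to 1114. Of 100 splits, 2 gave at least the 3 genes, but the highest other, 731, points to sample structure beside the niche genotype. Chance alignment with it cannot be excluded. Nor can chance for the 0 lists (100 of 100 splits, highest other 9). Among libraries with 4-digit numbers 1 of 84 splits gave the 882 genes and the highest other 653, so such alignment stays open.

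For EC, 4 genes became 7 when not robust, 7 with limma voom, 2 with the 6 EC libraries alone and 7 with exon length removed, and 2 to 22 with 1 library left out. The genes changed where the count did not: no filter and 5 CPM kept 2 and called 2 lower, 20 counts kept 3 and called 1 lower, and thinning kept 1 and called 1 lower. DESeq2 gave 6, kept 3 and called 2 lower. For OBC, 14 became 3 without haemoglobin, immunoglobulin, mitochondrial and sex-linked genes, 6 after thinning, 9 with exon length removed and 3 to 16 with 1 library left out. For MSC, 5 became 9 with RLE, 0 with no filter, 0 with the 5 CPM filter, 24 with the filter at 20 counts, 18 without haemoglobin, immunoglobulin, mitochondrial and sex-linked genes, 36 with DESeq2, 59 with limma voom, and 71 with the 6 MSC libraries alone. They became 1 after thinning, 15 without genes that overlap ribosomal RNA, 17 with exon length removed and 0 to 16 with 1 library left out. For the average, 34 became 14 with no filter, 15 with the 5 CPM filter, 62 with limma voom, 13 after thinning and 14 to 71 with 1 library left out. The interaction count of 6 became 10 with no filter and 2 to 15 with 1 library left out. With no filter, 440 genes of EC and 506 of OBC against the other populations became 880 and 789; with 1 library left out they ran from 391 to 546 and from 487 to 607, and the 74 of MSC from 38 to 94. The 14 lists past camera became 2 with an estimated correlation, 7 with fry, 28 with no filter and 10 to 19 with 1 library left out. The mean Wnt5a level of the LSK Wnt5a libraries, 0.857 CPM with TMM-scaled totals, ran from 0.613 to 1.09 with 1 library left out. Thinning left 200 genes tested, which limits what it can call; the cause of the other shifts was not tested.

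Niche numbers that lie 6 apart (such as MSC 1, OBC 7 and EC 13) may mark sets of 3 libraries from 1 animal, which the labels do not say. Deviations from the group means correlated by -0.0620 to 0.173 within a set, over 0.1 in 7 of 18 pairs, and the best match was of the own set in 30 of 36 checks, a hint from the data, not the design. With the set as a block in limma voom, 10 genes passed in EC, 60 in MSC and 49 in the average. With the mean of each set as 1 sample (limma trend, 3 against 3), 17 passed in the average, S100a9 and Ngp among them and Kitl not. With the set as a block in edgeR, the interaction kept its 6 genes.

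Among genes of the naming rule that passed (2 LSK, 4 EC, 11 OBC, 5 MSC, 20 average), no alternative turned a direction. In alternatives other than a library left out, the call was kept in 17 of 24 cases for LSK, 44 of 54 for EC, 118 of 131 for OBC, 50 of 63 for MSC and 200 of 248 for the average. Other named genes gained a call there in 23 of 192 cases for LSK, 0 of 266 for EC, 1 of 274 for OBC, 44 of 286 for MSC and 10 of 223 for the average. With 1 library left out, calls were kept in 5 of 22 cases for LSK, 18 of 24 for EC, 35 of 66 for OBC, 12 of 30 for MSC and 281 of 360 for the average.

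Directions turned for genes that never passed: Jun in OBC (-0.01) was 0.000673 with limma voom and 0.255 after thinning, and Jun in MSC (0.34) was -0.0547 after thinning. With 1 library left out, log2 fold changes ran from -0.46 to 0.24 for Rhoa in EC, -0.57 to 0.24 for Cdc42 in EC, -0.14 to 2.13 for Vcam1 in EC, -2.35 to 0.19 for Ppp3ca in OBC, and -0.40 to 0.26 for Jun in OBC. They ran from -0.00296 to 0.97 for Jun in MSC, -0.70 to 0.0477 for Ppp3ca in MSC, -0.48 to 3.83 for Spp1 in MSC and -0.80 to 0.0414 for Ppp3ca in the average; the cause was not tested.

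Splits of 3 against 3 libraries are too few for a share under 0.05. In EC, 3 of 10 splits gave at least the real 4 genes (highest other 25) and 9 at least the real 3 lists (highest other 5). In OBC, 1 of 10 gave the real 14 genes (highest other 1) and 2 the real 5 lists (highest other 5). In MSC, 1 of 10 gave the real 5 genes (highest other 1) and 2 the real 3 lists (highest other 4). For the average, with each library split on its own, chance can be excluded for the 34 genes (1 of 100 splits, highest other 4) and not for the 3 lists (35 of 100, highest other 5). By share alone it can be excluded for the 6 interaction genes (2 of 100, highest other 8). Splits that keep the sets together are also too few: 1 of 10 gave the 34 genes (highest other 4), 1 the 6 interaction genes (highest other 1) and 3 the 3 lists (highest other 4). Chance can be excluded for the 440 genes of EC (1 of 100, highest other 163) and 506 of OBC (1 of 100, highest other 184) against the other populations. By share alone it can for the 74 of MSC (4 of 100), but another gave 168.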

Other observations

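The tests of this part were set before their results were seen, but the set of libraries and the exon length trend they concern were noticed in the data first.

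Among the LSK libraries with 4-digit label numbers, further genes changed in the Wnt5a niche that the report does not describe. The membrane skeleton gene Epb41l3 was higher (log2 fold change 1.90, SE 0.22, edgeR adjusted p = 0.000987), as were Arhgap11a, a GTPase-activating protein of dividing cells (1.66), the chromatin protein gene Ptma (1.41) and the mitochondrial genes mt-Atp6 (1.73) and mt-Nd6 (1.89). The nuclear export gene Xpo4 (-3.10, SE 0.38, edgeR adjusted p = 0.00137), Tspan4 (-2.26), Nudt19 (-2.21) and Fbxo45 (-1.95) were lower. The G2/M genes Kif23 (0.77) and Top2a (0.56) were higher and the G1/S genes Chaf1b (-1.12) and Gins2 (-1.92) lower, and 3 of 36 tested genes of oxidative phosphorylation were lower, Sdhd (-0.93), Sdhc (-1.19) and Atp5c1 (-0.94). The integrin Itgav was higher (0.98, edgeR adjusted p = 0.0231) and the adaptor gene Crkl lower (-2.78, edgeR adjusted p = 0.0191). These lists did not pass camera as a whole (adjusted p = 0.215 for G2/M, 0.423 for G1/S, 0.511 for oxidative phosphorylation and 0.359 for integrins and focal adhesion). Whether their members passed more often than the 882 of 13910 over all genes was not tested. Xist (-1.10, edgeR adjusted p = 0.0175) and its antisense gene Tsix (1.54, edgeR adjusted p = 0.0281) changed in opposite directions. Whether strand was used in counting is not given, so counts under Tsix need not be antisense RNA. In Wnt5a replicates 4 and 5, which lie outside this set, Epb41l3 was at 152 and 17.6 CPM and the B cell gene Cd79a at 3.02 and 133 CPM.

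The 425 genes higher in this set had longer exons (median 4802 bases) than the 457 lower ones (2385 bases), with 3880 bases over all genes tested; 98.9% of them had a length. Across genes, which are not independent replicates, the Spearman correlation of length with the log2 fold change was 0.225, and -0.0109 once each library's trend with exon length was removed. Among the genes that passed after removal, the length difference turned, with medians of 2785 bases for higher and 3602 bases for lower genes. A length trend as the whole cause is argued against: 719 of the 882 genes still passed without it, among 1029 that passed in all (639 higher, 390 lower). Wasf2 (1.17, edgeR adjusted p = 0.0193) and Arhgef7 (1.30, edgeR adjusted p = 0.0113) were among those 719. Depth as the cause is argued against by the median size of the 882 log2 fold changes, 1.39 (SE 0.324) with the library total as a covariate and 1.41 before. The niche genotype, the satellite and mitochondrial reads of the same Wnt5a libraries, label order and other differences between these animals may each contribute. They were not told apart for these 882 genes, of which 727 passed with the library total as a covariate.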
